A study of Mus musculus with 6 samples.

How the data were processed

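RNA was sequenced from 6 mouse liver tumours, 3 with wild-type Gli1 and 3 with Gli1 knocked out, all from SULF2-overexpressing animals. Libraries were assigned to genotypes from the sample titles, which also number the replicates 1 to 3. The numbers opening the sample descriptions were 1759, 4204 and 3981 for WT replicates 1, 2 and 3, and 1767, 4206 and 1647 for the KO replicates. The labels do not say whether each tumour came from a separate animal, so p-values of the single-gene tests measure only the spread between these samples.

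The authors deposited 1 table with a raw read count and an RPKM value for each of 43346 genes in each library. Per the submitters' processing notes, bcl2fastq, TopHat2 2.0.6 and HTSeq were named, without roles, together with the human builds hg19 and GRCh37. The deposited gene identifiers are nevertheless mouse Ensembl identifiers. Of the 42462 identifiers shared with the GENCODE M21 annotation of GRCm38, 84.2% had the same start position and 99.8% started within 100 kb, so coordinates are given as deposited and read as GRCm38. The strand used in counting is not given in the sources used here. The deposited RPKM values were scaled by a coding length and by a library total that lay 12.6 to 19.0% above the summed gene counts. They were used only to check the table. All 37 mitochondrial rows held 0 in every library, so the list of mitochondrially encoded genes could not be assessed.

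Summed gene counts ranged from 75205624 to 132979502 reads per library. The 10 genes with the most counts took 26.1 to 33.5% of a library, and Alb alone took 12.6 to 15.1%. No pair of libraries held identical counts. Intervals on counts are exact Poisson or binomial intervals at 95% and cover counting error only.

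Deposited counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the genotype, libraries were scaled by TMM factors, and the robust quasi-likelihood test was applied, two-sided, with Benjamini-Hochberg adjustment over the 18359 genes kept and a threshold of FDR 0.05 without a fold minimum. Log2 fold changes are KO minus WT with their standard errors. Gli1 fell below the filter and was added back for its own value. Normalized CPM are CPM computed on the TMM-scaled library size.

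Before the data were examined, 36 lists of pathway genes and cell type markers were fixed, with a further list of sex-linked genes as a label check. Of the 617 list entries, 611 matched a deposited symbol, 3 matched through the GENCODE name of the identifier and 3 had no match. The 35 lists with at least 3 genes kept were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Adjustment was over the 35 lists. The preset test takes its degrees of freedom from the number of genes, so its p-values do not measure the spread between tumours. Camera with an estimated correlation, which takes them from the libraries, and fry were run as alternatives. Members were also adjusted over the list alone. List means and medians are over edgeR log2 fold changes.

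Genes were named by a rule fixed in advance. It took Gli1 and Sulf2, up to 10 genes in each direction among those past FDR 0.05 and, since fewer than 10 passed, the 10 genes of smallest p. It also took the 2 members of smallest p in each list described at length, of which some are not reported here. Pim1 and Apcs, which passed after adjustment over their list alone, Saa1 to Saa4, the list members called by DESeq2 and the genes named only in the closing section were chosen after their values were seen.

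Alternatives fixed in advance were RLE and upper-quartile factors, DESeq2 1.42.0, limma voom, no low-count filter, a CPM of at least 1 in 3 libraries, the replicate number as a block, a covariate for the range of the number opening the sample description, a non-robust fit, removal of the 10 most counted genes, an FDR of 0.1, a log2 minimum of 1 and leaving out each library. DESeq2 gave a p-value for 28057 genes, and its own filtering left fewer of them in the adjustment. The number-range covariate set WT replicate 1 and KO replicates 1 and 3, with numbers under 2000, against the rest, with numbers above 3900. It was therefore not balanced between genotypes. A covariate of 1 surrogate variable from sva 3.50.0, voom with sample quality weights and DESeq2 on the genes kept for edgeR were added after seeing the data.

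The tests were tried on simulated counts drawn from the real means, library sizes and dispersions of 18359 genes, 200 of them changed. For KO versus WT, edgeR recovered 1.5% of 2-fold, 56.7% of 4-fold and 86.4% of 8-fold changes, and 5.9% of its calls were false. DESeq2 recovered 17.9%, 89.6% and 98.5% of the same sizes, and 32.8% of its calls were false. Camera recovered 3 of 3 lists shifted 2-fold and called 0 others, with genes simulated as independent. Estimated correlations in the real lists reached 0.855, so this does not show how often correlated lists are called falsely.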

Results

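Gene expression was measured by RNA sequencing in liver tumours induced with diethylnitrosamine (DEN), a liver carcinogen, in mice that overexpress SULF2. SULF2 is an extracellular sulfatase that edits heparan sulfate chains. The comparison asks how loss of GLI1, a zinc finger transcription factor at the end of the Hedgehog pathway, altered these tumours. There were 3 Gli1 WT and 3 Gli1 KO libraries. Total counts of WT replicates 1, 2 and 3 were 88659131, 75205624 and 95777670 reads, and those of KO replicates 1, 2 and 3 were 95808696, 132979502 and 76746128.

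Gli1 (ENSMUSG00000025407, minus strand of chromosome 10, 127329889 to 127341589) was counted at a very low level in every tumour. WT replicates 1, 2 and 3 had 10, 20 and 7 reads, and the KO replicates had 4, 3 and 3. Each KO library was below each WT library, in the direction of the labels. The log2 fold change was -2.24 ± 0.65 (SE, n = 3 per group), with an unadjusted edgeR p of 0.0112, which did not pass edgeR's adjustment (FDR 1). Summed over libraries there were 37 reads among 259642425 in WT and 10 among 305534326 in KO, a ratio of 0.23 (95% exact interval 0.102 to 0.471, counting error only). A two-sided exact permutation test of the CPM gave p = 0.1, the smallest that 3 against 3 samples allow. The labels do not say which part of the gene was deleted, so whether the KO reads lie outside it is not known.

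Sulf2 varied far more between tumours of one genotype than between genotypes. Normalized CPM were 76.4, 11.6 and 5.33 in WT replicates 1, 2 and 3, against 164.5, 2.63 and 10.2 in the KO replicates. The log2 fold change of 0.93 ± 1.56 (SE, n = 3 per group) did not pass (edgeR FDR 1). It was -2.27 without KO replicate 1 and 2.81 without WT replicate 1. Whether the transgene is of human or mouse sequence is not given in the labels, so these counts may not cover it.

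**Figure D1:**
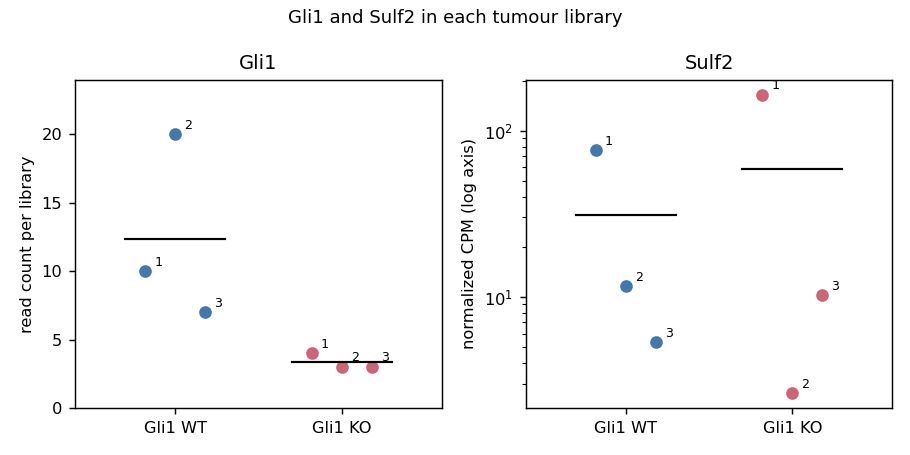
Read counts of Gli1 (left, linear axis from 0) and normalized CPM of Sulf2 (right, log axis) in the 3 Gli1 WT and 3 Gli1 KO tumours. Points are libraries marked with their replicate number and bars are group means. All KO libraries lie at 3 or 4 Gli1 reads, whereas Sulf2 overlaps between genotypes.

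No single gene passed FDR 0.05 in edgeR's quasi-likelihood test between Gli1 KO and WT tumours. Of 18359 genes, 0 passed and the smallest FDR was 0.407. At an unadjusted p under 0.05 there were 665 genes, 294 higher and 371 lower in KO, where 918 are expected by chance. Without WT replicate 3 that number was 1779 (939 by chance), with 0 past FDR 0.05. The groups did not overlap for 1489 genes (8.11%, against 10% by chance). DESeq2, which gave a p-value for 28057 genes and adjusted over fewer, called 64, 23 higher and 41 lower. It had 1090 at an unadjusted p under 0.05 where 1403 are expected by chance. A fit with 1 surrogate variable called only Socs3 (FDR 0.0166), and limma voom called 0.

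The 10 genes of smallest p, none of which passed edgeR's adjustment, had all KO libraries on one side of all WT libraries. Picking by small p favours such genes, so this is not added evidence. Socs3 (ENSMUSG00000053113, chromosome 11, 117966079 to 117970047), the feedback inhibitor of cytokine signalling through STAT3, had normalized CPM of 44.5, 40.6 and 63.5 in WT and 9.29, 5.91 and 6.61 in KO (log2 fold change -2.77 ± 0.27, FDR 0.407). Cxcl1, a chemokine that attracts neutrophils, had 113, 132 and 97.0 CPM in WT and 25.1, 10.6 and 8.93 in KO (-2.94 ± 0.43). Nfil3, a basic leucine zipper repressor of the clock, averaged 25.2 ± 5.04 (SD, n = 3) CPM in WT and 7.05 ± 1.23 in KO. Also lower in KO were the integrin subunit Itgb3 at -1.86 ± 0.28, the kinase Map3k8 at -1.64 ± 0.25, the neutrophil gene Retnlg at -2.65 ± 0.36 and the serpin Serpina3a at -4.70 ± 0.68. Higher in KO were the carboxylesterase Ces2h at 3.40 ± 0.38, Iffo2 at 1.09 ± 0.15 and the homeobox gene Hoxb6 at 3.41 ± 0.57. Ces2h, Serpina3a and several Mup genes called by DESeq2 belong to families of close paralogs, so their counts are uncertain. Hoxb6 stayed under 1 CPM in all libraries.

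**Figure D2:**
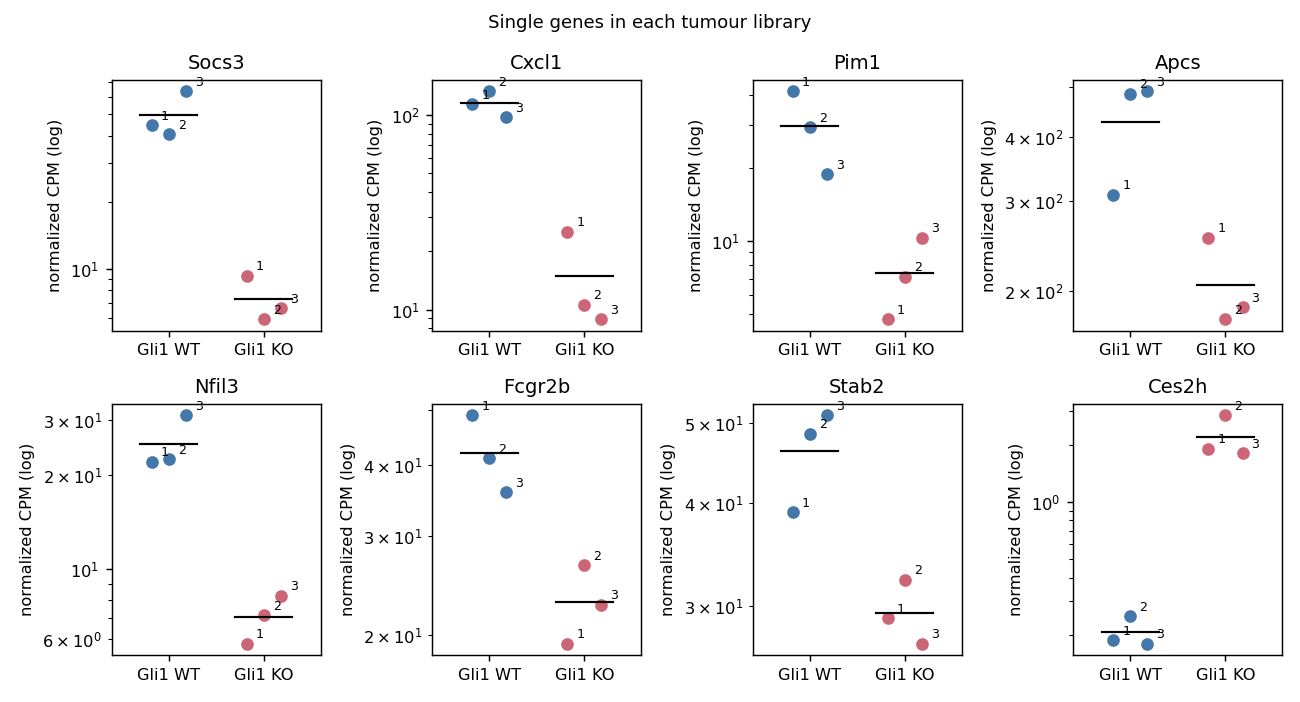
Normalized CPM (log axes, scaled per gene) of 8 genes in each Gli1 WT and Gli1 KO tumour. Points are libraries marked with their replicate number and bars are group means. Socs3 lies at 40.6 or above in WT and at 9.29 or below in KO. No gene shown overlaps between genotypes, which picking by small p favours. None passed edgeR's adjustment over all genes, while DESeq2 called Socs3, Cxcl1, Pim1, Nfil3 and Ces2h.

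Among the gene lists, 13 of 35 passed FDR 0.05 by camera with the preset correlation, 9 lower and 4 higher in KO. None of the 13 calls held with an estimated correlation (smallest adjusted p = 0.197) or by fry's directional test. Fry's mixed test, for change in either direction, gave FDR 0.0069 for the acute-phase list. Within every list, 0 members passed over all genes tested by edgeR. DESeq2 called Socs3 (adjusted p = 9.48e-14), Cxcl1 (1.51e-07) and Pim1 (0.00281) of the acute-phase list, Retnlg (4.19e-08) of the neutrophil list and Nfil3 (2.91e-07) of the circadian list. It also called Mup7 (0.00108) of the male-biased list and Cyp8b1 (0.0422) of the bile acid list, which both overlapped between genotypes. WT replicate 3 had 0.91 CPM of Mup7 against 0.68 to 1.77 in KO, and 4.74 CPM of Cyp8b1 against 6.41 to 14.8.

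Acute-phase and STAT3 response genes fell in the Gli1 KO tumours. Of 23 members, 21 were negative and 8 had all KO libraries below all WT libraries, with a median log2 fold change of -0.63 (camera FDR 3.15e-11). With an estimated correlation, adjusted p = 0.197. Adjusted over the list alone, 4 members passed, all lower in KO. They were Socs3 and Cxcl1, the STAT-induced kinase Pim1 (-2.01 ± 0.39) and the pentraxin Apcs (-1.06 ± 0.28), a plasma protein made by hepatocytes. The serum amyloid members did not pass, with Saa1 at -0.53 ± 0.73, Saa2 at -0.42 ± 0.97, Saa3 at 0.13 ± 0.91 and Saa4 at -0.52 ± 0.41. In the same libraries the leukocyte lists were lower in KO.

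Endothelial markers fell as well, with 13 of 16 members negative, a median of -0.46 and 9 members without overlap (camera FDR 1.69e-06). With an estimated correlation, adjusted p = 0.197. Adjusted over the list alone, the sinusoidal Fc receptor Fcgr2b (-0.87 ± 0.19) and the scavenger receptor Stab2 (-0.65 ± 0.16) passed.

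All 4 leukocyte lists fell by the preset test. T and NK cell markers had 15 of 16 members negative, a median of -1.02 and FDR 2.68e-09 (adjusted p = 0.464 with an estimated correlation). Gzmb, a granule protease, had -1.64 ± 0.39 and the T cell receptor component Cd3d had -1.62 ± 0.47, both under 1 CPM. B and plasma cell markers had 10 of 11 negative, a median of -0.94 and FDR 1.70e-05 (adjusted p = 0.197 with an estimated correlation), with the B cell receptor component Cd79a at -1.39 ± 0.41 and the kinase Blk at -1.37 ± 0.46. Their mean log2 fold change of -0.89 shrank to -0.43 without WT replicate 3. Neutrophil markers had 10 of 10 negative, a median of -1.86 and FDR 1.30e-05 (adjusted p = 0.631 with an estimated correlation). Retnlg passed over the list alone and the calprotectin subunit S100a9 had -1.83 ± 0.64 (-1.01 without WT replicate 3). Without WT replicate 3 the neutrophil call was lost (mean -0.19 against -1.86, FDR 0.0704). The mean was -3.05 without KO replicate 1 and -0.92 with quality weights. Macrophage and Kupffer cell markers had 13 of 16 negative, a median of -0.61 and FDR 0.0194 (adjusted p = 0.827 with an estimated correlation), with Timd4 at -2.84 ± 0.90 and the scavenger receptor Cd163 at -1.99 ± 0.74. Without WT replicate 2 these were -1.33 and -1.29, and Cd163 was -1.24 with the number-range covariate. That call was lost without WT replicate 2 (mean -0.28 against -0.80, FDR 0.334), WT replicate 3 (FDR 0.506) or KO replicate 1 (FDR 0.18).

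Extracellular matrix and stellate cell genes rose by the preset test, in the opposite direction to the endothelial and leukocyte lists. The genotypes did not overlap for 1 member. Of 26 members, 23 were positive, with a median of 0.64 (camera FDR 2.05e-06, adjusted p = 0.631 with an estimated correlation). Desmin (Des), an intermediate filament of stellate cells, had 1.13 ± 0.35 and the receptor Pdgfrb had 0.84 ± 0.36 (1.28 without WT replicate 3). The list mean of 0.72 became 1.43 without WT replicate 3, 0.46 without WT replicate 1, 0.39 without KO replicate 1 and 1.10 with quality weights.

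Cell cycle genes rose by the preset test, with 28 of 30 positive and a median of 0.71 (FDR 6.32e-05, adjusted p = 0.827 with an estimated correlation). The call depended on KO replicate 3, where the replication helicase gene Mcm6 had 37.2 CPM against 2.55 to 7.42 in the other libraries. The transcription factor E2f1 had 1.64 ± 0.63 and Mcm6 1.71 ± 0.75, against 0.66 and 0.48 without that library. Without KO replicate 3 the list mean fell from 0.77 to 0.03 (FDR 0.369), and without WT replicate 2 it was 0.49 (FDR 0.104). It was 1.43 without WT replicate 3, 1.15 without KO replicate 2 and 0.39 with the number-range covariate.

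Lipid synthesis genes also rose by the preset test, although 0 members of either list were free of overlap between genotypes. Fatty acid synthesis had 14 of 16 positive, a median of 0.68 and FDR 0.00199 (adjusted p = 0.597 with an estimated correlation), with Acaca at 0.72 ± 0.34 and Fasn at 1.18 ± 0.61 (1.18 and 2.07 without WT replicate 3). Cholesterol synthesis had 20 of 21 positive, a median of 0.33 and FDR 0.00462 (adjusted p = 0.827 with an estimated correlation), with Dhcr7 at 0.95 ± 0.61 (0.53 without WT replicate 2 and 1.68 without WT replicate 3). The fatty acid call was lost without KO replicate 3 (mean 0.29 against 0.55, FDR 0.207). The cholesterol mean of 0.34 was -0.05 without KO replicate 1 (FDR 0.382), -0.004 without WT replicate 2 (FDR 0.9) and 0.19 without WT replicate 1. It was larger at 1.12 without WT replicate 3 (FDR 2.49e-07), 0.60 without KO replicate 2, 0.72 with quality weights and 0.53 with voom or the replicate block. Its call was also lost with the number-range covariate (FDR 0.0796) or 1 surrogate variable (FDR 0.0541).

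Genes listed for proteins secreted by hepatocytes fell by a small amount, with 18 of 20 negative, a median of -0.26 and FDR 0.00496 (adjusted p = 0.331 with an estimated correlation). That list also held Hnf4a, Cebpa and Tat, whose products are not secreted. The fibrinogen chains Fgg (-0.73 ± 0.33) and Fga (-0.83 ± 0.41) had the smallest p, and were -0.43 and -0.33 without WT replicate 3 (Fga -0.48 with quality weights). The call was lost without WT replicate 1 (FDR 0.0913). Hypoxia and glycolysis genes had 16 of 20 negative, a median of -0.26 and FDR 0.0194 (adjusted p = 0.631 with an estimated correlation), with the glucose transporter Slc2a1 at -0.67 ± 0.22 and Pgk1 at -0.37 ± 0.18 (-0.24 without WT replicate 3). Their mean of -0.22 was 0.02 without WT replicate 3 (FDR 0.587) and -0.14 without KO replicate 2 (FDR 0.184). It was -0.34 without KO replicate 1 and -0.14 with quality weights (FDR 0.0947).

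Female-biased liver genes had 13 of 16 negative, a median of -0.92 and FDR 0.013 (adjusted p = 0.631 with an estimated correlation), with the monooxygenase Fmo2 at -1.90 ± 0.52 and the transcription factor Cux2 at -4.24 ± 1.43. WT replicate 2 stood apart, with 78.0 CPM of Cux2 against 0.36 to 10.1 elsewhere. Without it Fmo2 was -1.12, Cux2 -1.94 (-2.62 with the number-range covariate) and the list mean -0.16 against -1.22 (FDR 0.18), and the call was also lost without KO replicate 1 (FDR 0.162), without WT replicate 3 (FDR 0.1), with the number-range covariate (FDR 0.0796), 1 surrogate variable (FDR 0.0687) or quality weights (FDR 0.0667). The macrophage call was lost under the same 3 settings (FDR 0.233, 0.0564 and 0.268), and its mean was -0.28 with the covariate and -0.31 with quality weights. All 6 tumours expressed the Y-linked genes Ddx3y (37.6 to 71.2 CPM), Uty and Eif2s3y, with 4 to 29 reads of Xist.

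**Figure D3:**
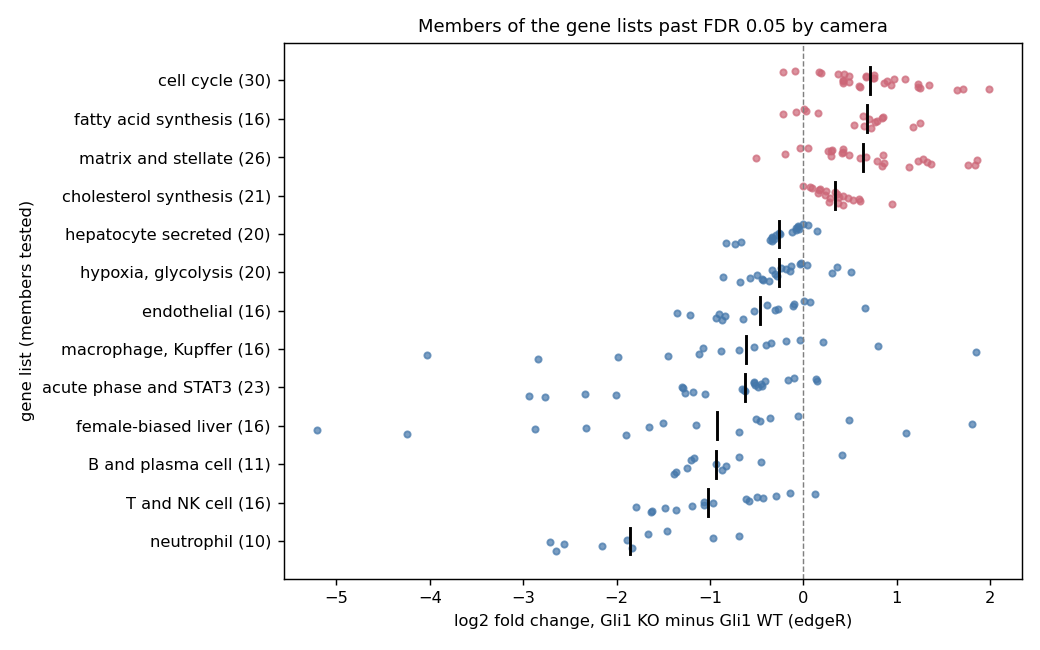
Log2 fold changes (Gli1 KO minus WT, edgeR) of the members of the 13 gene lists past FDR 0.05 by camera with the preset correlation. Each point is a gene, black bars are list medians, and the number of members tested is in brackets. Medians run from -1.86 for neutrophil markers to 0.71 for cell cycle genes.

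The Hedgehog pathway list did not pass. Of 13 members tested, 10 were positive, with a median of 0.32 and a mean of 0.26 (camera FDR 0.109). The mean was -0.05 without KO replicate 1 (median 0.04, FDR 0.953), -0.001 without KO replicate 3, 0.10 without WT replicate 3, 0.40 without WT replicate 2 and 0.08 without the low-count filter. The ligand Ihh had 1.86 ± 0.60, with 0.22 to 2.11 CPM over the 6 libraries. Genes reported as GLI targets did not pass either, with 7 of 16 positive and FDR 0.962. Their median was -0.06 and their mean 0.04, which ran from -0.34 without KO replicate 1 to 0.65 without WT replicate 3. Among them Ccnd1 (cyclin D1) had 1.28 ± 0.61 and Vegfa had -0.43 ± 0.21, against 0.81 and -0.28 without WT replicate 2. Heparan sulfate genes had 15 of 26 positive, a median of 0.02, a mean of -0.01 and FDR 0.701, and the mean ran from -0.34 without KO replicate 1 to 0.34 without WT replicate 3. The core proteoglycan Sdc4 had -0.95 ± 0.26, with 425 to 684 CPM in WT and 243 to 306 in KO, and the heparanase Hpse had -0.80 ± 0.36. Oncofetal liver tumour genes had 9 of 18 positive, a median of -0.09, a mean of 0.33 and FDR 0.701, with Sox4 at 1.46 ± 0.76 and Scd2 at 1.54 ± 0.82 (2.57 and 2.72 without WT replicate 3). Their mean ran from -0.96 without KO replicate 1 to 1.67 without WT replicate 3, and was -0.04 with 1 surrogate variable.

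The other 18 lists tested did not pass either. By camera FDR they were pancreatic acinar markers (0.067), interferon response (0.13), periportal genes (0.139), NRF2 targets (0.176), fatty acid oxidation (0.196), endoplasmic reticulum stress (0.304), bile acid, xenobiotic metabolism and growth factor signalling genes (0.306 each), circadian clock (0.363), TGF-beta and mesenchymal genes (0.58), p53 response (0.673), antigen presentation (0.701), Wnt and pericentral genes (0.725), MAPK output and male-biased liver genes (0.734 each), cholangiocyte markers (0.766) and erythroid markers (0.962). In the circadian list Nfil3 passed adjusted over the list alone (0.00139). Many of these depended on 1 library or on the fit. Endoplasmic reticulum stress passed as lower in KO with the number-range covariate (FDR 0.0174) and interferon response as higher with quality weights (FDR 0.00754). Male-biased genes took opposite directions, lower in KO without WT replicate 3 (mean -1.04, FDR 0.00462) and higher without WT replicate 2 (mean 0.40, FDR 0.017). Without WT replicate 3, camera FDR was also 0.00602 for bile acid and 0.0397 for acinar genes, both lower, and 0.00351 for interferon, 0.0239 for oncofetal, 0.00645 for MAPK, 0.0464 for p53 and 0.0132 for TGF-beta genes, all higher. Without WT replicate 2 it was 2.61e-06 for Wnt and pericentral genes, which were higher, and 0.000513 for endoplasmic reticulum stress and 0.00324 for acinar genes, which were lower. The remaining calls were all lower in KO. Without WT replicate 1, FDR was 0.0092 for both NRF2 and xenobiotic genes. Leaving out KO replicate 2 gave 0.041 for fatty acid oxidation, 0.0274 for periportal and 1.37e-05 for acinar genes. Leaving out KO replicate 1 gave 0.00398 for endoplasmic reticulum stress, and leaving out KO replicate 3 gave 0.0145 for periportal genes.

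Genotype did not separate the tumours along the main axis of variation. The first principal component (42.7% of variance) placed WT replicate 3 at 80.9 and KO replicate 1 at 65.2. Apart from them lay WT replicates 1 and 2 at -49.3 and -67.9 and KO replicates 2 and 3 at -7 and -22. On the second component (19.3%), KO replicates 1, 2 and 3 lay at 16.1, 14.7 and 52.4, above the WT replicates at 13.6, -58.5 and -38.3. That separation was narrow between WT replicate 1 and KO replicate 2, and 10% is the share expected by chance. Pearson correlations of log2 CPM across genes were 0.923 to 0.960 within WT, 0.952 to 0.967 within KO and 0.926 to 0.966 between genotypes, and genes are not independent replicates.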

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

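The surrogate variable, the quality weights and DESeq2 on edgeR's genes were chosen after seeing the data. The count of 0 genes past FDR 0.05 became 64 with DESeq2, which gave 28057 genes a p-value but adjusted over fewer. It was 63 with DESeq2 on the 18359 genes kept for edgeR and 1 with 1 surrogate variable, and 0 under every other alternative run. Simulated on 18359 genes, DESeq2 gave 32.8% false calls, against 5.9% for edgeR. The count of 13 lists became 0 with an estimated correlation and 0 by fry's directional test, whereas fry's mixed test gave FDR 0.0069 for the acute-phase list. The estimated correlation of each of the 13 was above the preset 0.01, but only at 0.017 for endothelial and 0.016 for hepatocyte-secreted genes. Their camera p still rose, from 1.45e-07 to 0.00723 and from 0.00142 to 0.0378. Correlation alone may therefore not explain the loss of calls. The 2 forms of camera also differ in degrees of freedom, taken from the genes with the preset correlation and from the libraries with an estimated one. With few libraries this raises p as well. The share of each was not tested, nor was the cause for fry. Under the other alternatives the count of lists was 10 to 17, and 11 to 17 with 1 library left out. Gli1 stayed negative throughout, from -1.64 without WT replicate 2 to -2.57 without WT replicate 3. Sulf2 turned negative with voom (-0.038), the number-range covariate (-0.74), 1 surrogate variable (-1.15) and quality weights (-1.13), and ran from -2.27 to 2.81 with 1 library left out. The cause was not tested beyond those left-out libraries.

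With the replicate block, 0 genes passed (502 at an unadjusted p under 0.05), 13 lists passed and Gli1 was -2.12. Same-numbered libraries did not deviate together (r = -0.29, 0.18 and -0.34 across genes), and the labels do not say that a number marks a shared litter or day. A sex covariate was not run, since all libraries show Y-linked expression. The non-robust fit does not alter camera, and T and NK markers had too few genes left at a CPM of 1. Gli1 rests on 3 to 20 reads per library, and Hoxb6 was at 0.03 to 0.60 CPM.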

Other observations

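WT replicate 3 and KO replicate 1, which lie together on the first principal component, had the highest levels of the oncofetal gene Afp, at 52.8 and 273.6 CPM against 5.20 to 23.6 in the other libraries. WT replicate 2 had high pericentral genes, with Cyp2e1 at 5294 CPM against 391 to 1050 elsewhere and Slc1a2 at 126 CPM against 5.47 to 16.5. The Kupffer cell receptor Marco was at 55.4 CPM in that library and at 0.41 to 3.72 elsewhere. WT replicate 1 and KO replicate 2 had the highest pancreatic acinar transcripts, with Ctrb1 at 41.8 and 21.8 CPM against 2.37 to 5.06. Slc7a11 reached 57.5 CPM in WT replicate 3 and stayed under 1 elsewhere. KO replicate 3 had 1.44 CPM of the Y-linked Kdm5d against 12.5 to 17.0 in the others, and also the lowest Ddx3y (37.6 against 46.4 to 71.2) and Uty (10.6 against 12.1 to 17.4), with Eif2s3y (37.1) within the range of the others. These genes were picked after their values were seen.

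Tests of the acute-phase, leukocyte and endothelial patterns were chosen only after those results were seen, and the splits and the Gli1 neighbourhood test were set before. The bounds of these later tests were also changed once their values were known. At first 2 standard errors were required, and then 3, since 3 libraries per group give an imprecise standard error. The earlier bound would have counted 2 results as evidence against their explanations, hepatocyte-secreted members (2.09 standard errors) and matrix minus endothelial genes (2.43). Under the later bound both are left open. The result for hepatocyte-secreted members also assumed that fewer leukocytes would leave them unmoved, which was not tested. The left-out test first dropped only WT replicate 2 (endothelial difference -0.58 ± 0.09) and was widened to each WT library.

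The 6 libraries split into 3 and 3 in 10 ways, too few for a share under 0.05. By edgeR the real split gave 0 genes and the highest other split 1. All 10 splits give at least 0, so this count says nothing about chance. With DESeq2 the real split gave 64 genes and the highest other 1042, with 5 splits at 64 or more. That highest split set WT replicates 1 and 2 and KO replicate 3 against the rest, which points to a structure of the samples other than genotype. For lists, the real split gave 13 and the splits that mix genotypes gave 9 to 19, with 4 of the 10 splits at 13 or more. A count of 13 is thus within what groupings other than genotype gave. The acute-phase list had its smallest camera p in the real split, and also had a camera p under 0.05 in 3 of the 9 splits that mix genotypes.

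The fall of acute-phase and STAT3 genes could reflect fewer leukocytes, or less stress at collection, as well as the genotype. Members secreted by hepatocytes were lower by -0.77 ± 0.37 (SE, mean log2 CPM) with no overlap, although WT replicate 1 (7.69) and KO replicate 3 (7.68) nearly touched. Whether fewer leukocytes would leave these members unmoved was assumed and not tested, so fewer leukocytes remain open whatever the bound. Immediate-early genes differed by -0.24 ± 0.97, which cannot tell a difference in collection from none. A response of the tumours to loss of Gli1 is a hypothesis that these data leave untested against both.

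The lower endothelial, lymphocyte and myeloid markers may each rest on 1 WT tumour. Against this, the endothelial difference of -0.50 ± 0.11 kept at least -0.44 whichever WT library was left out. The groups did not overlap with all libraries in, so leaving a library out could not make them overlap. Lymphocyte markers (-0.77 ± 0.29) kept at least -0.61, but KO replicate 1 (-0.598) overlapped WT replicate 2 (-0.622) with all libraries in. The bound also required no overlap, so this stays open. That overlap does not itself bear on whether 1 WT tumour carries the difference. Myeloid markers (-0.86 ± 0.68) shrank to -0.39 without WT replicate 3, so that tumour carried much of the pooled difference. WT replicate 2 (2.44) was high as well as WT replicate 3 (3.03), and WT replicate 1 (0.80) lay below every KO library (1.01 to 1.40). The 2 lists also rested on different tumours. The macrophage mean log2 fold change shrank most without WT replicate 2 (-0.28), and the neutrophil mean without WT replicate 3 (-0.19). A lower share of all non-parenchymal cells would lower matrix genes with endothelial genes. These moved apart by 1.36 ± 0.56 without overlap, although WT replicate 3 (-0.85) and KO replicate 2 (-0.82) nearly touched. The difference is under the later bound and leaves that explanation open.

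Sequence next to the targeted Gli1 allele could come from another strain and carry expression differences. Within 10 Mb of Gli1, 4 of 148 genes tested had an unadjusted p under 0.05 (2.7%, against 3.6% elsewhere). The odds ratio was 0.74 (95% interval 0.20 to 1.94, two-sided Fisher's exact test p = 0.823). This argues against an odds ratio of 2 or more for genes at that p. It does not exclude differences too small to reach that p, and neighbouring genes are not independent.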
